A study of Mus musculus with 4 samples.

How the data were processed

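Peripheral lymph node dendritic cells of 1 group of mice were measured in 2 droplet captures, and each capture gave 2 libraries, 1 of gene expression and 1 of antibody tags, 4 libraries in all. Per the labels' protocols, the cells were loaded with 10x Genomics 3' chemistry, with TotalSeq-B antibodies and 1 capture lane per sample. The submitters' processing notes list Cell Ranger 8.0.1, bcl2fastq 2.20.0, STAR 2.7.2a and the genome build GRCm39, without saying which step each served. The names R1 and R2 of the deposited lists are those that the sample titles carry, and this was the basis for assigning each list to a capture. The labels do not say whether the captures came from separate animals, so a difference between them may be technical.

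The 5 deposited files used were text lists with no measured values. They were a list of cell barcodes and a list of features for each capture, and a table of the antibody panel. The file names call the barcodes filtered, but neither the step nor the criteria of that filtering are given in the sources used here. Whether doublets or poor-quality cells had been removed is therefore unknown. Matrices of counts were not analysed here. Depth per cell, genes per cell, doublets, cell types, subset shares and expression were therefore not assessed, and the tests between subsets planned before the data were examined were not run. The only depth that could be given is the number of cell barcodes per capture. No columns of per-sample values were left unused.

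Barcodes were compared by sequence after removal of the suffix that numbers the capture. The number shared between captures was given an exact Poisson 95% interval, and the share of R2 barcodes an exact Clopper-Pearson 95% interval. The size of the barcode pool was estimated from the shared number by Chapman's capture-recapture formula. Base composition was compared by a two-sided permutation test of the capture labels with 100000 resamples, using the largest absolute difference in base share over positions as the statistic. The barcode methods were tested on simulated data. Over 100 simulated pairs of draws from a pool of 360000 barcodes, the Poisson interval held the expected shared number in 95, and the median capture-recapture estimate was 363817. In the permutation test of composition, simulated captures without a difference gave p = 0.205 and captures with an altered first base gave p = 0.000999, the smallest value that run could give. Each setting was a single run, and the alteration was not matched to the difference observed between the captures. The power of the test for a difference of that size is therefore not known.

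Each antibody was matched to its coding gene by a table written by hand from the established names of the antigens, and these genes were then looked up by symbol in the gene features. The antibody clones' isoform specificity was not considered in this match, nor was whether the mouse strain displays each antigen. Of the 33696 gene identifiers, 31961 (94.9%) were found in a separate table of gene names, 29374 of them with the same symbol, and 248 genes carried their identifier in place of a symbol. Symbols are those of the deposited feature lists. No genome or annotation of GRCm39 was used here, so no coordinates are given. Distances between antibody tags were counted as differing positions over the 15 bases of the tag. The panel table places 10 random bases before each tag.

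The lists of cell type markers (13) and of functions (7) and the rule for naming genes were fixed before the data were examined. In the absence of values per cell, the rule named every antibody target whose gene is in a list, every isotype control and the pairs of tags at the smallest distance. The members of the B cell list are not reported here. The pairs at the next distance, the targets named outside the lists and the genes without an antibody were chosen after the data were seen. Alternatives concerned the matching of barcodes, the composition statistic, counting by identifier or symbol, the distance measure and the matching of antibodies to genes. Computations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and the plot was drawn with Matplotlib 3.10.9.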

Results

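Dendritic cells, the antigen-presenting cells that display peptides to T cells, were taken from the peripheral lymph nodes of C57BL/6 mice aged 16 weeks and profiled by CITE-seq. In CITE-seq, each cell's polyadenylated RNA and the DNA tags of antibodies bound to its surface are read under the same cell barcode. The labels described 1 population, sorted on CD11c and on the MHC class II molecules I-A/I-E after T and B cells had been depleted. It was loaded in 2 captures, named R1 and R2, and each capture gave a gene expression library and an antibody library. The labels named no treatment, genotype or control arm. The comparisons open to the design were therefore between dendritic cell subsets within a capture and between the captures. The title places the study's question in which dendritic cell subset regulates the homeostasis of naive CD8 T cells. Counts of RNA molecules or antibody tags per cell were not analysed here, so no level of any gene or protein, no subset share and no difference between subsets is given. What follows describes the number of cell barcodes, the genes and proteins that the assay looked for, and how the captures compared in their barcodes. The gene features are a list of what was looked for and do not show that a gene was detected in any cell.

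For each dendritic cell subset with a marker list, the panel held an antibody against the product of at least 1 listed gene. The marker lists also contain genes for intracellular and secreted proteins, such as Irf8, Batf3, Fscn1 and Ccl22, which a surface antibody is not made to read. The share of a list covered therefore depends on how the list was made and does not rank the subsets. The panel comprised 85 antibodies, of which 77 were directed at a target and 8 were isotype controls, antibodies with no intended target that measure non-specific binding. For conventional type 1 dendritic cells (cDC1), which cross-present antigen to CD8 T cells, 3 of 11 listed marker genes had an antibody against their product. These were Xcr1 (a chemokine receptor), Itgae (CD103) and Cd24a (CD24). CD8α, which lymph node-resident cDC1 also carry and which was listed among the T cell markers, was in the panel as well. For conventional type 2 dendritic cells (cDC2), 6 of 10 listed genes were covered, namely Sirpa (CD172a), Itgam (CD11b), Clec10a (CD301a), Mgl2 (CD301b), Cd4 and Itgax. Itgax codes for CD11c, which was part of the sort gate and is shared by the other dendritic cell subsets.

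For plasmacytoid dendritic cells, the main producers of type I interferon, 4 of 9 listed genes were covered. These were Siglech, Bst2 (CD317), Ly6c2 and Ptprc. Ptprc, which leukocytes in general express, was read by 3 antibodies, against CD45, CD45.2 and the B220 form. Of the Langerhans cell list, which describes the dendritic cells of the epidermis, 3 of 4 genes were covered by antibodies to CD207, CD326 (Epcam) and CD1d. Of the list for migratory dendritic cells, which reach the node from peripheral tissue and which holds mostly genes for intracellular or secreted proteins, 1 of 10 genes was covered. That gene was Cd83. Ccr7, the chemokine receptor that guides this migration, and Fscn1, an actin-bundling protein, were in the gene features but had no antibody in the panel.

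T cells, which the depletion was meant to leave out, and other cell types beside dendritic cells were also represented in the panel. Antibodies covered 5 of 8 T cell genes (Cd3e, Cd4, Cd8a, Cd5 and Thy1) and 2 of 6 genes of natural killer or innate lymphoid cells (Klrb1c, read by the NK1.1 antibody, and Il7r). They covered 5 of 11 monocyte or macrophage genes, which were Csf1r (CD115), Adgre1 (a macrophage adhesion receptor), Fcgr1 (CD64), Siglec1 (CD169) and Ly6c1, 2 of 5 neutrophil or granulocyte genes (Ly6g and Siglecf) and 1 of 7 stromal or endothelial genes (Pecam1). No plasma cell gene and no proliferation gene, of 4 in each list, had an antibody. Each antibody matched to Ly6c1 was also matched to Ly6c2 of the plasmacytoid dendritic cell list, so these antibodies do not separate the lists. Over the 13 lists of cell type markers, 33 of 96 distinct genes were covered. These counts leave out panel targets that were in no list, among them CD14, CD163, CD204, MERTK, Tim-4 and CD49b. They therefore do not give the panel's full coverage of these cell types.

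**Figure D1:**
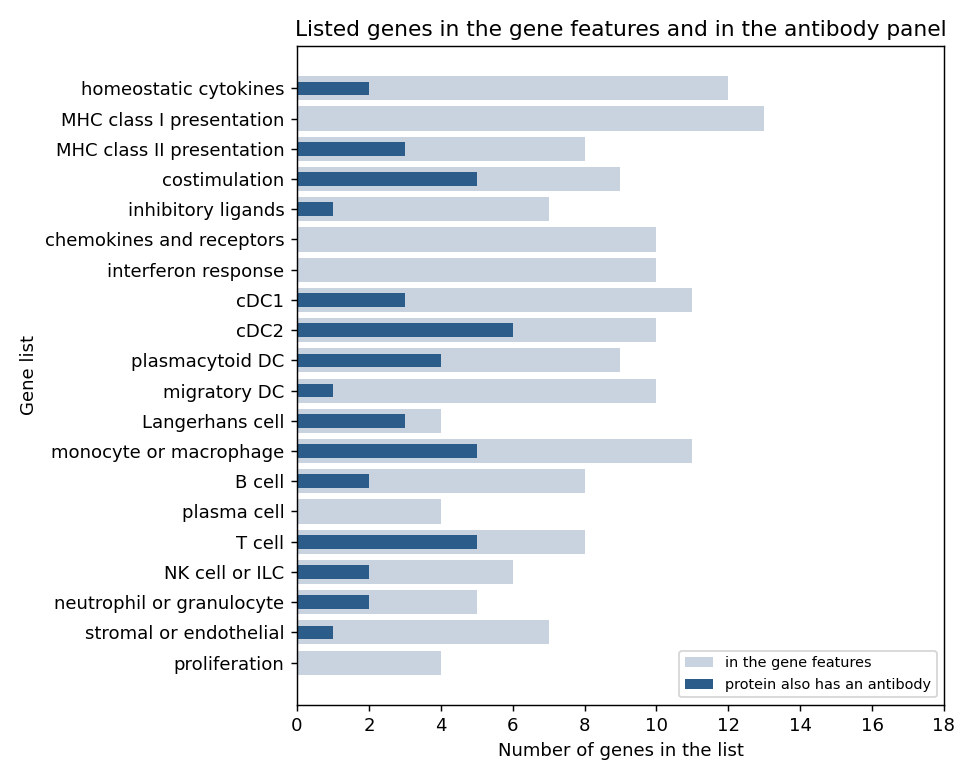
Horizontal bars give, for each of the 20 gene lists on the vertical axis, the number of its genes in the gene features (light bars) and the number whose protein also had an antibody in the panel (dark bars). The light bars reach the full length of each list, whereas the dark bars range from 0 genes in 5 lists to 6 genes in the cDC2 list.

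Over 7 lists of genes by which dendritic cells present antigen to T cells, sustain them or respond to signals, 11 of 69 distinct genes had an antibody, and here too many members code for intracellular or secreted proteins. Among the homeostatic cytokine genes, 2 of 12 had an antibody, and both code for receptor chains, Il7r (CD127) and Il2ra (CD25). Il15 and Il15ra, the cytokine and the receptor chain that presents it to T cells, and Il7 were in the gene features but had no antibody in the panel. None of the 13 genes of MHC class I presentation, such as H2-K1, H2-D1, B2m and Tap1, and none of the 10 chemokine and chemokine receptor genes or the 10 interferon response genes had one. These zeros cover the listed genes only. The chemokine receptor gene Xcr1, which had an antibody, was listed under cDC1. Of the 9 costimulation genes, 5 were covered, namely Cd80, Cd86, Cd40, Cd48 and Icam1 (CD54). Cd274 (PD-L1) was the covered member of the 7 inhibitory ligand genes. Of 8 genes of MHC class II presentation, 3 were matched to an antibody, namely H2-Aa, H2-Ab1 and H2-Eb1. An antibody to I-A/I-E was matched to each of them, and another to I-Ab was matched to H2-Aa and H2-Ab1. The match to H2-Eb1 rests on the antigen's name and does not show that these mice display I-E.

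All 161 distinct genes of the 20 lists were present in the gene features, which reflects the annotation used and not these cells, and none had a symbol that a second gene also used. Of the 77 targets, 76 were matched to coding genes in the gene features, and TER-119, an erythroid antigen, was assigned none. These 76 antibodies corresponded to 76 distinct genes, since 6 antibodies were matched to more than 1 gene and 7 genes were matched to more than 1 antibody. The genes with several antibodies were Ptprc, Spn (CD43 and its activation-associated glycoform), H2-Aa, H2-Ab1, Ly6g, Ly6c1 and Ly6c2. The Ly6C antibody was matched to both Ly6c1 and Ly6c2, near-identical genes, and the Ly6G/Ly6C antibody to Ly6g as well, so their signals cannot be assigned to 1 of these genes. Of the 77 targets, 33 lay outside the 20 lists, among them CD135, the Flt3 receptor on which dendritic cell development depends, CD117 (Kit), CD44, CD62L and CD304.

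The 8 isotype controls were the clones G0114F7, HTK888, MOPC-173, MOPC-21, MPC-11, RTK2071, RTK2758 and RTK4530. All 85 antibody tags were 15 bases long and distinct. Among the 3570 pairs of tags the median number of differing positions was 11 and the smallest was 4, found in 1 pair. That pair was CD103 (TTCATTAGCCCGCTG) and CD61 (TTCTTTACCCGCCTG). At 5 differing positions there were 5 pairs, namely CD61 with XCR1, CD304 with CD45.2, CD48 with CD54, the MOPC-21 control with CD88, and the RTK2071 control with the CD43 glycoform. A single misread base therefore could not turn any tag of the panel into another.

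The deposited lists of the captures held similar numbers of cell barcodes. Capture R1 held 11324 cell barcodes and capture R2 held 10996, a difference of 328, which together made 22320 barcodes, 50.7% of them in R1 and 49.3% in R2. With 1 count per capture there was no replicate error against which to test this difference, and the number of cells loaded was not given in the sources used here. The feature lists of the captures were identical in all 33781 rows, 33696 genes and 85 antibodies. Lists made from a common annotation and panel are identical whatever the cells contain, so this shows only that the captures can be joined row by row, and the 85 antibody rows matched the panel table in identifier and name. The genes carried 33670 distinct symbols, because 26 symbols, among them Ddit3, Aldoa, Ptp4a1 and Nnt, were each used by 2 identifiers. Ddit3, a stress-response transcription factor, and Aldoa, a glycolytic enzyme, would therefore be split or merged depending on whether identifiers or symbols are used. The list held 13 mitochondrially encoded genes.

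Of the barcodes of R2, 39 also occurred in R1, which is 0.355% (exact binomial 95% interval 0.252% to 0.485%). The base composition of the barcodes did not differ detectably between the captures. The largest difference at any of the 16 positions was 1.51 percentage points, for G at position 5 counted from the first base, with 23.5% in R1 and 22.0% in R2 (two-sided permutation test of the largest difference over all positions and bases, 100000 resamples, p = 0.409). These intervals and tests cover counting error only. Barcodes are drawn from a common kit pool, so their composition does not show whether the cells of the captures are alike.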

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

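Of 13 alternatives over 10 results, 9 were labelled as leaving the result the same, and 4 moved it. A count was the same if it stayed near its main value, and the tag distance only if equal. The pool had to stay in its range and the composition p-value on the same side of 0.05. Ignoring case could not raise the 85 panel names or the 161 listed genes, which were already complete. Leaving out the 39 shared barcodes, and counting 33670 symbols in place of 33696 identifiers, changed too little to move a count. The tally therefore does not measure how robust the results are. The smallest distance between antibody tags fell from 4 to 3 when insertions and deletions were allowed, again for CD103 and CD61 alone. Matching antibody names to gene symbols exactly gave 0 of 77 targets, and matching them without regard to case, an alternative chosen after the data were seen, gave 20, against 76 with the hand-written table. Comparing the barcodes of one capture with the reverse complement of the other gave 0 shared barcodes, against 39 in the same orientation. Allowing 1 mismatch left the number at 39. Within each capture no barcode lay 1 mismatch from another, so this alternative had little room to add any. The composition test gave p = 0.407 without the shared barcodes and p = 0.495 on the first 2 bases (permutation tests).

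No paired analysis was possible because the lists hold no measured values per library. For the same reason the alternatives set out beforehand for genes, antibodies and cell subsets (normalization, low-count filter, doublets, clustering resolution, cell filters, pseudocount and leaving out a capture) were not run.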

Other observations

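The tags of CD103 and XCR1, both markers of cDC1, each lay near the tag of CD61 (Itgb3, an integrin chain), at 4 and 5 differing positions. Both 4 and the 3 edits found with insertions and deletions allowed exceed a single error. No counts were analysed here that would show whether reads were exchanged among these tags.

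The pool rebuilt from parts of the barcodes, and the tests of chance and carry-over that rest on it, were chosen after the shared barcodes had been seen. The first 8 and last 8 bases of the 22320 barcodes formed 3824 and 3814 distinct sequences. Linking the first and last parts that occurred together in a barcode split them into 4 groups with no part in common, which held 5616, 5577, 5508 and 5580 of the distinct barcodes. If every combination within a group is in the kit, the pool would hold 3646226 barcodes, inside the range of 2335560 to 4489941 that corresponds to the Poisson interval of the 39 shared barcodes (capture-recapture estimate 3113525). From that pool 34.2 shared barcodes are expected by chance, and the 95% interval of the observed 39 runs from 27.7 to 53.3. This restates the comparison of pool sizes as a number of barcodes and is not a separate result. The number shared is consistent with random draws from 1 pool of this structure. Carry-over of barcodes from one capture into the other stays open, since the lower bound of 27.7 lies below the chance value, and the interval leaves room for up to 19.2 barcodes beyond chance. No biological explanation was tested. A join of the captures by barcode sequence alone would merge 39 pairs of cell barcodes.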
